A study of Xenopus tropicalis with 10 samples.

How the data were processed

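Tail tissue of stage 40 *Xenopus tropicalis* tadpoles was sequenced as 10 libraries made, per the labels' protocols, from total RNA with an Illumina TruSeq kit. The submitters' processing notes name Trim Galore 0.3.3, TopHat2 2.0.13, SAMtools 1.1, HTSeq, DESeq2 and R 3.2.0, without their roles. The genome build and annotation are not given in the sources used here, so no coordinates are printed. The values the authors deposited are a normalised signal per gene, 26550 genes by 10 libraries, in a table that also holds the authors' own cluster and flag of change, whose test and threshold are not stated. Every value of a library was a whole multiple of what 1 read is worth there (100% of values at a tolerance of 0.01). Median-of-ratios size factors computed from the recovered reads matched those steps to within 2.7e-11, so the deposited signal is gene reads divided by DESeq2 size factors. No row lacked a gene name. Symbols other than locus identifiers were present for 11086 genes (41.8%).

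The test planned before the data were examined, for raw counts, was edgeR's quasi-likelihood test. Because the deposited values are normalised signal, limma (3.58.1, in R 4.3.3) was used in its place on log2(value + 1), with a trend of variance on mean, after keeping genes with at least 10 normalised reads in at least 2 libraries (17896 genes). The pseudocount and this filter were set once the unit was known and before any test result. edgeR (4.0.16) and DESeq2 (1.42.0) were run on the recovered reads as alternatives. Fold changes are on the log2(value + 1) scale and understate the change of low genes. All 10 libraries entered a single fit with 6 group levels and 4 residual degrees of freedom, which gives the single libraries at 6 and 15 hpa the spread of the 4 duplicated groups. Genes with Benjamini-Hochberg adjusted p under 0.05 were called.

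Gene lists (31, with 797 symbols) and the rules for naming genes were fixed before the data were examined. A list symbol matched a gene of the same symbol, ignoring case, or the symbol with a copy number; 642 symbols were in the table, 646 genes were tested in a list, and 10 of them were in more than 1 list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation and fry, which tests whether a list's genes move in a common direction. fry called 3, 0, 2, 2, 5 and 0 lists in the comparisons of 0 hpa with the whole tail, 6, 15, 24 and 72 hpa with 0 hpa, and 72 with 24 hpa. Genes named per comparison are the 5 largest rises and falls with a symbol, at least 5 CPM in the higher group and no overlap between the groups' libraries; for the 6 lists with the smallest camera p, up to 3 called members; and a panel of genes fixed in advance. Some genes that met these rules are not used here. Other named genes are said to be chosen after their values were seen, or are the remaining called members of a list.

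The scripts were tested on simulated counts with 50 genes changed at each of 4 sizes. For 24 against 0 hpa (17800 genes), limma recovered 12%, 68%, 92% and 94% of genes changed by 1, 2, 3 and 4 log2 units, and 13 of its 146 calls were false. For 15 against 0 hpa (17784 genes) it recovered 2%, 46%, 82% and 88%, and 16 of 125 calls were false. Both false shares are above what the 0.05 threshold allows on average. DESeq2 made 48 false calls among 199 and 60 among 186 in the same simulations. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 93.45 to 210.8), so none was counted as a duplicate. The simulated overlap and kept signs of lists of the observed sizes were added after the observed values had been seen. Intervals and floors of 3 reads cover counting error only. Alternatives tried were other scalings, filters, pseudocounts, test tools and sets of libraries, thinning to 1 depth, the whole tail as the reference, a replicate block and leaving out each replicate of a duplicated group.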

Results

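RNA was sequenced from tail tissue of stage 40 tadpoles of *Xenopus tropicalis*, a frog whose tadpoles can regrow an amputated tail. The 10 libraries fell into 6 groups. The whole tail group (2 libraries) was the tail removed by a first amputation. The 0 hpa group (hours post amputation, 2 libraries) was the tissue beside that wound, removed from the same animals by a second cut straight after the first. Regenerating tails were collected at 6 hpa (1 library), 15 hpa (1 library), 24 hpa (2 libraries) and 72 hpa (2 libraries). The design text speaks of duplicates, but 1 library each was analysed here at 6 and 15 hpa. These are the 2 deepest libraries, and whether each merges a duplicate is not given in the sources used here; if so, each value is a pool, and the tests that treat it as a single library mean something else. No uncut tadpoles of the age reached at 72 hpa formed a group. Nothing in the labels says that replicates came from separate animals or pools, so p-values measure the spread between these libraries, which may be technical.

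Gene reads per library, recovered from the deposited values, ranged from 15966579 (72 hpa replicate 2) to 128768239 (6 hpa). The 15 hpa library held 121670034, and the other 7 libraries between 22114681 and 58467586. A count of 3 reads corresponded to 7.29 normalised reads in the shallowest library and to 0.852 in the deepest. Globin genes, transcribed in red blood cells, made up 0.774% and 0.614% of the reads in the whole tail libraries, 1.36% and 4.17% at 0 hpa, 0.964% at 6 hpa, 0.459% at 15 hpa, 0.596% and 0.381% at 24 hpa, and 0.122% and 0.303% at 72 hpa. Skeletal muscle genes took 1.77% and 0.317% of the reads in the whole tail libraries and 0.388% and 1.86% in the 72 hpa libraries. They took 1.31% and 0.517% at 24 hpa, but 0.792% and 0.789% at 0 hpa. Replicates thus differed in this share in every duplicated group except 0 hpa. The first principal component (39.3% of the variance) ran from the whole tail and 0 hpa libraries to the 72 hpa libraries, and the second carried 12.9%.

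The comparison of 0 hpa with the whole tail asked how the tissue at the wound differed from the tail that had been removed. As groups, Hox and tailbud genes were lower beside the cut and injury-response, blood and leukocyte genes were higher (adjusted p between 0.13 and 0.32 with an estimated correlation), while no single gene passed the limma test. The 21 tested anterior and trunk Hox genes, which encode transcription factors of the body axis, were all lower in fitted value, with a median log2 fold change of -1.36. The 14 posterior Hox genes were likewise all lower, with a median of -1.23. For these lists camera gave adjusted p = 4.9e-20 and 7.5e-12 (adjusted p = 0.13 and 0.29 with an estimated correlation). Adjusted over the list alone, 17 of the 21 and 7 of the 14 were lower. Of 18 tailbud progenitor genes, 17 had lower values (median -1.36, camera adjusted p = 2.1e-12; adjusted p = 0.13 with an estimated correlation), and 11 were lower adjusted over the list alone.

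Among the tailbud genes, MSGN1, a regulator of presomitic mesoderm, had a log2 fold change of -6.06 (SE 1.86) and NKX1-2 one of -5.07 (SE 1.15), with limma adjusted p = 0.46 and 0.31 over all genes. These examples, and NOT and IL1B below, were chosen after their values were seen. All 19 FGF signalling genes had lower values (median -0.72, camera adjusted p = 9.9e-08; adjusted p = 0.26 with an estimated correlation). FGF20, a secreted growth factor, stood at 31.35 ± 17.8 normalised reads at 0 hpa (SD, n = 2) against 131.6 ± 36.5 in the whole tail (SD, n = 2; limma adjusted p = 0.31). Notochord and floor plate genes had a median of -0.22 (camera adjusted p = 8.5e-05; adjusted p = 0.29 with an estimated correlation). NOT, a homeobox gene of the notochord, had a log2 fold change of -1.25 (SE 0.194, limma adjusted p = 0.24) and was among the 4 genes lower adjusted over the list alone.

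In the other direction, 20 of 21 inflammatory genes were higher in value at 0 hpa (median 1.24, camera adjusted p = 6.2e-11; adjusted p = 0.29 with an estimated correlation), 13 of them adjusted over the list alone. IL1B, a cytokine released on injury, had a log2 fold change of 3.49 (SE 0.649, limma adjusted p = 0.26). SOCS3, a feedback inhibitor of cytokine signalling, averaged 6878 ± 2320 normalised reads (SD, n = 2) against 1656 ± 330 (SD, n = 2; limma adjusted p = 0.35). Of 20 immediate early genes, induced within minutes of a stimulus and many of them encoding transcription factors, 19 were higher in value (median 0.99, camera adjusted p = 5.9e-10; adjusted p = 0.29 with an estimated correlation). Leukocyte genes had a median of 0.73 (20 of 23 higher in value, camera adjusted p = 4.6e-11; adjusted p = 0.18 with an estimated correlation). MPO, a peroxidase of myeloid cells, averaged 2608 ± 149 against 1119 ± 110 (SD, n = 2 each; limma adjusted p = 0.31). All 19 erythroid genes were higher in value (median 1.37, camera adjusted p = 1.2e-10; adjusted p = 0.32 with an estimated correlation), beside the larger globin share of the 0 hpa libraries. Of all 31 lists, 6 were called higher and 10 lower by camera. The other calls were matrix proteases and ribosome biogenesis (higher) and myogenic progenitors, neural progenitors, Wnt signalling, Notch signalling and pigment cells (lower), with adjusted p between 0.26 and 0.78 with an estimated correlation. Of these, only the matrix protease call held in every fit without a library. The myogenic and neural progenitor calls were also lost after thinning every library to the depth of the shallowest. Without whole tail replicate 1, the myogenic progenitor, neural progenitor and pigment cell medians were 0.18, 0.0156 and -0.175. Without 0 hpa replicate 2, the ribosome biogenesis median was -0.0152. With an estimated correlation, no list passed in any of the 6 comparisons.

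With limma on log2(value + 1), 0 of 17896 genes passed (1422 had an unadjusted p under 0.05). On the recovered reads edgeR with TMM called 2 genes lower, AIF1L (-3.67) and EMX1 (-2.38), but 0 with DESeq2 size factors, and DESeq2 called 198 higher and 128 lower. Without whole tail replicate 2, 3 genes were called higher, without 0 hpa replicate 1, 1 higher and 1 lower, and 6 of the 16 list calls ended in at least 1 fit without a library.

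The comparison of 6 hpa with 0 hpa followed the first hours after the cut. As lists, immediate early genes were lower at 6 hpa and leukocyte and matrix protease genes higher (adjusted p = 0.4, 0.29 and 0.29 with an estimated correlation), and no single gene passed. Of 20 immediate early genes, 17 had lower values (median -2.06, camera adjusted p = 2.2e-15; adjusted p = 0.4 with an estimated correlation), and 12 were lower adjusted over the list alone. Part of this fall lay in the 0 hpa reference, since the list median relative to the 0 hpa mean was -1.42 and -0.57 in the whole tail libraries. EGR1, a zinc finger transcription factor of this list, had a log2 fold change of -2.30 (SE 0.265, limma adjusted p = 0.11). FOS had one of -3.02 (SE 0.882, limma adjusted p = 0.66); both were chosen after their values were seen. Leukocyte genes had a median of 1.03 (19 of 23 higher in value, camera adjusted p = 2.3e-10; adjusted p = 0.29 with an estimated correlation). Matrix proteases, which break down extracellular matrix, had a median of 0.58 (camera adjusted p = 0.0012; adjusted p = 0.29 with an estimated correlation). Of these, MMP9 stood at 6179 normalised reads in the 6 hpa library and at 1459 ± 232 at 0 hpa (SD, n = 2; limma adjusted p = 0.33). MMP11 had a log2 fold change of 4.15 (SE 0.496, limma adjusted p = 0.11), an example chosen after its value was seen.

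HMOX1, the heme oxygenase induced by oxidative stress, was listed at 4861 normalised reads at 6 hpa against 809.2 ± 402 at 0 hpa (SD, n = 2) and 881.5 at 15 hpa. Its log2 fold change at 6 hpa was 2.68 (SE 0.414, limma adjusted p = 0.26). The oxidative stress list of 22 tested genes, which holds HMOX1, had a median of 0.06 at 6 hpa and was not called. Ribosome biogenesis genes had a median of 0.49 (20 of 22 higher in value, camera adjusted p = 0.00019; adjusted p = 0.97 with an estimated correlation). Erythroid genes had a median of -1.39 (camera adjusted p = 5.2e-08; adjusted p = 0.83 with an estimated correlation), but 0.31 with the whole tail as the reference. The remaining camera calls were lower. They were DNA replication (median -0.48) and neural progenitors (-0.74), with adjusted p = 0.83 with an estimated correlation. Notch signalling (-0.63), unfolded protein response (-0.36), oxidative phosphorylation (-0.25) and mitosis genes (-0.20) were the others, each with adjusted p = 0.97 with an estimated correlation.

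At 6 hpa limma called 0 genes (1044 had an unadjusted p under 0.05), edgeR called 0, and DESeq2 called 101 higher and 41 lower. The test assumes that the single 6 hpa library varies like the duplicated groups. Without the low-count filter limma called 121 genes higher and 10 lower, and without whole tail replicate 1 it called 2 higher. Of the 11 list calls at 6 hpa, those for mitosis, ribosome biogenesis and unfolded protein response genes were lost without 0 hpa replicate 1, the last also against the whole tail (median -0.27). The mitosis call was also lost after thinning every library to the depth of the shallowest.

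**Figure D1:**
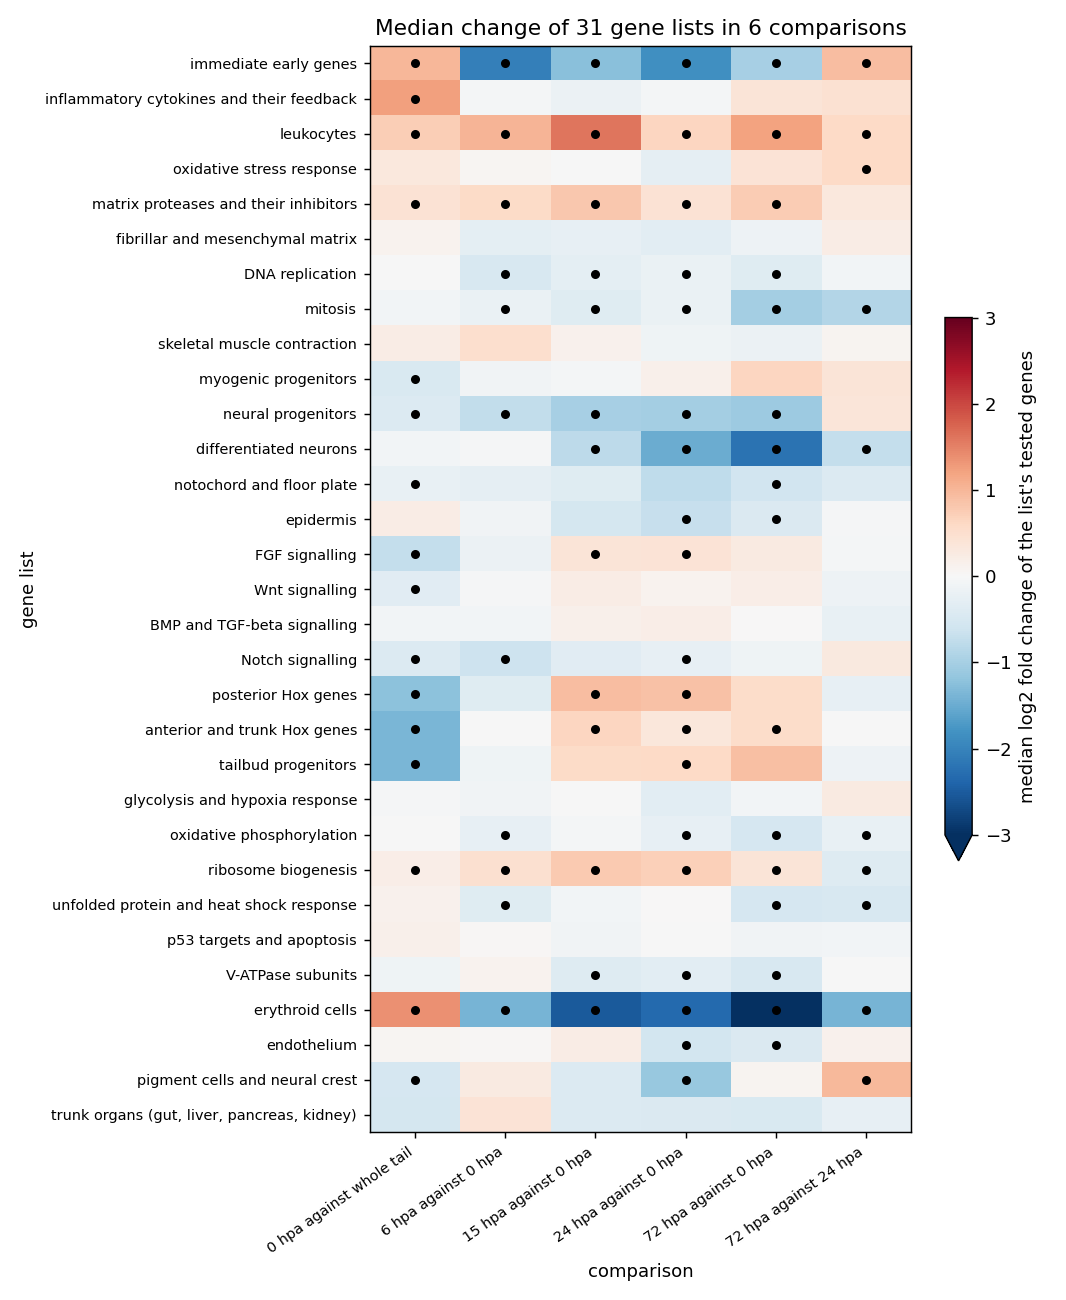
Median log2 fold change of the tested genes of each of 31 gene lists (rows) in 6 comparisons (columns), on a colour scale from -3 (blue) to 3 (red); black dots mark camera calls at the preset correlation. Leukocyte genes were called higher in all 6 columns, and the erythroid median went from 1.37 at 0 hpa against the whole tail to -3.75 at 72 hpa against 0 hpa.

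In the comparison of 15 hpa with 0 hpa, leukocyte and matrix protease lists were called higher (adjusted p = 0.2 with an estimated correlation for both), and KRT18L, FN1, ITGAX and KRT16 were among the single genes that rose. KRT18L, a keratin, had the largest rise of the genes that met the rule for naming (a symbol, enough reads and no overlap between groups), from 103.7 ± 0.972 normalised reads at 0 hpa (SD, n = 2) to 5389 (log2 fold change 5.69, SE 0.464, limma adjusted p = 0.013). FN1, which encodes the matrix protein fibronectin, rose by 3.72 (SE 0.36), and ITGAX, a leukocyte integrin, by 3.51 (SE 0.452), with limma adjusted p = 0.026 and 0.041. KRT16, another keratin, rose by 3.81 (SE 0.508, limma adjusted p = 0.041), to 269400 normalised reads. The whole tail held 281600 ± 32200 (SD, n = 2), and the log2 fold change of KRT16 against it was -0.06. Only 3 genes with symbols met the rule for naming falls: WNT10B, a secreted Wnt ligand (-3.20, SE 0.466), NDC80, a kinetochore protein (-2.18, SE 0.217), and ZNF687 (-1.61, SE 0.227), with limma adjusted p = 0.049, 0.026 and 0.045. WNT10B (-2.20) and ZNF687 (-1.30) did not pass against the whole tail.

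Of 23 leukocyte genes, 3 rose at 15 hpa and 20 did not pass, while 16 were higher adjusted over the list alone. The list median was 1.61 (camera adjusted p = 1.6e-12; adjusted p = 0.2 with an estimated correlation). The 3 were CSF1R, the receptor of macrophage colony-stimulating factor (1.88, SE 0.198), RAC2 (1.73, SE 0.253) and LCP1 (1.72, SE 0.208). Of 17 matrix protease genes, 3 rose, namely MMP9 (3.02, SE 0.346), MMP7 (2.66, SE 0.321) and MMP14 (1.33, SE 0.186). The list median was 0.80 (camera adjusted p = 5.4e-05; adjusted p = 0.2 with an estimated correlation). Erythroid genes had a median of -2.52 with 15 of 19 lower adjusted over the list alone, and immediate early genes one of -1.25. For these camera gave adjusted p = 2.1e-10 and 6.3e-08 (adjusted p = 0.71 with an estimated correlation for both). Relative to the 0 hpa mean, the erythroid median was already -1.02 and -1.79 in the whole tail libraries. Neural progenitors (-0.99), differentiated neurons (-0.79) and V-ATPase subunits (-0.38) had lower medians (adjusted p = 0.71 with an estimated correlation for each). Ribosome biogenesis (0.79), posterior Hox (0.92), anterior and trunk Hox (0.64) and FGF signalling genes (0.38) had higher ones (adjusted p = 0.71 with an estimated correlation for each). Against the whole tail the posterior Hox, anterior and trunk Hox and FGF medians were -0.42, -0.76 and -0.16, and the immediate early median was -0.40 with its call lost (camera adjusted p = 0.18). Mitosis and DNA replication genes had medians of -0.38 and -0.30 (adjusted p = 0.73 with an estimated correlation for both).

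In all, limma called 41 genes higher and 24 lower at 15 hpa, edgeR 68 and 16 with TMM or 48 and 12 with DESeq2 size factors, and DESeq2 410 and 417. These calls assume that the single library varies like the duplicated groups, and every fit without 1 library made fewer. There were 0 and 1 without 0 hpa replicate 1, 0 and 2 without 0 hpa replicate 2, 12 and 9 without either whole tail replicate, 7 and 4 without either 24 hpa replicate, 4 and 4 without 72 hpa replicate 1, and 5 and 4 without 72 hpa replicate 2. Of the 13 list calls, 3 were lost in at least 1 fit without a library, those for DNA replication, FGF signalling and V-ATPase genes.

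By 24 hpa FN1, the keratin genes KRT18L and KRT16 and the growth factor gene FGF20 had risen against 0 hpa, and neuron and immediate early lists were called lower with 6 and 3 genes falling (adjusted p = 0.53 with an estimated correlation for both). FN1 rose from 16140 ± 4060 to 263600 ± 57500 normalised reads (SD, n = 2 each; log2 fold change 4.04, SE 0.294, limma adjusted p = 0.0072). KRT18L rose by 4.87 (SE 0.379) and KRT16 by 4.12 (SE 0.415), with limma adjusted p = 0.0072 and 0.015. FGF20 rose from 31.35 ± 17.8 to 493.3 ± 146 (SD, n = 2 each; log2 fold change 4.02, SE 0.47, limma adjusted p = 0.021). VENTX2.1, a homeobox gene, rose by 4.03 (SE 0.602, limma adjusted p = 0.037) to 188.2 ± 22.5, beside 199.2 ± 130 in the whole tail (SD, n = 2 each). With the whole tail as the reference, KRT16, VENTX2.1 and FGF20 had log2 fold changes of 0.25, 0.08 and 1.89 and did not pass (limma adjusted p = 0.81, 0.96 and 0.11).

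Of 26 differentiated neuron genes 6 fell, 20 did not pass, and 16 were lower adjusted over the list alone. The list median was -1.48 (camera adjusted p = 5.1e-13; adjusted p = 0.53 with an estimated correlation). Those that fell included SLC18A3, the vesicular acetylcholine transporter (-2.73, SE 0.327), MNX1, a motor neuron homeobox gene (-2.48, SE 0.423), and ELAVL4, a neuronal RNA-binding protein (-2.23, SE 0.275). Of 22 neural progenitor genes 2 fell (median -1.03, camera adjusted p = 6.5e-06; adjusted p = 0.59 with an estimated correlation). They were DBX1, a homeobox gene of ventral neural progenitors (-5.44, SE 0.913), and FABP7, a fatty acid binding protein of radial glia (-3.85, SE 0.585). Of 20 immediate early genes 3 fell, KLF2 (-3.82, SE 0.491), EGR1 (-2.09, SE 0.216) and KLF6 (-1.10, SE 0.178), and 17 were lower adjusted over the list alone. The list median was -1.84 (camera adjusted p = 5.1e-13; adjusted p = 0.53 with an estimated correlation). Relative to the 0 hpa mean, the immediate early median was already -1.42 and -0.57 in the whole tail libraries. GP1BB, a platelet glycoprotein chain, and OTOS also fell (-3.40, SE 0.519, and -3.15, SE 0.533). Of these genes, GP1BB (-0.41), KLF6 (-0.62), EGR1 (-1.06), KLF2 (-1.92), FABP7 (-2.46), OTOS (-3.03) and DBX1 (-4.71) did not pass against the whole tail.

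Erythroid genes had a median of -2.34 at 24 hpa (camera adjusted p = 9.5e-12, and adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone 16 of 19 were lower, and 0 over all genes. Part of this fall lay in the 0 hpa reference. Relative to the 0 hpa mean, the list median was -1.02 and -1.79 in the whole tail libraries and -2.03 and -2.75 at 24 hpa. Ribosome biogenesis genes had a median of 0.72, with 14 of 22 higher adjusted over the list alone (camera adjusted p = 4.2e-09; adjusted p = 0.59 with an estimated correlation). Of 23 leukocyte genes 1, CSF1R, rose (1.33, SE 0.162; list median 0.64, camera adjusted p = 0.00011, adjusted p = 0.57 with an estimated correlation). Of 19 FGF signalling genes 2 rose, FGF20 and FGF8 (3.04, SE 0.484), with a list median of 0.42 (camera adjusted p = 0.0076; adjusted p = 0.59 with an estimated correlation). With the whole tail as the reference, the FGF median was -0.11. Of 17 matrix protease genes 3 rose (list median 0.43; adjusted p = 0.53 with an estimated correlation). Posterior Hox, tailbud and anterior and trunk Hox genes had medians of 0.89, 0.59 and 0.34 against 0 hpa (adjusted p = 0.61, 0.59 and 0.61 with an estimated correlation). Their medians against the whole tail were -0.57, -1.15 and -0.82. The 3 calls were lost without 0 hpa replicate 1 and without 24 hpa replicate 2, and the tailbud median was 0.05 in 24 hpa replicate 1 and 1.09 in replicate 2 (posterior Hox 0.33 and 1.21). Pigment cell (-1.13), epidermis (-0.70), endothelium (-0.55), V-ATPase (-0.31), oxidative phosphorylation (-0.25), Notch (-0.24), DNA replication (-0.21) and mitosis genes (-0.20) were the other calls, all lower. Their adjusted p was between 0.59 and 0.64 with an estimated correlation. Each of these 8 calls was lost in at least 1 fit without a library, as were 12 of the 19 list calls at 24 hpa. The Notch call held in 11 of 18 settings, the epidermis median was -0.30 against the whole tail with its call lost, and the pigment cell median was -0.42 in 24 hpa replicate 1 and -1.44 in replicate 2. In the same order, the medians were -0.90 and -0.16 for endothelium, -0.07 and -0.40 for oxidative phosphorylation, -0.20 and -0.48 for V-ATPase, -0.16 and -0.34 for DNA replication and -0.12 and -0.27 for mitosis genes.

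At 24 hpa limma called 119 genes higher and 54 lower, edgeR 89 and 38, and DESeq2 521 and 594. The limma calls rested on every library compared, with 0 and 0 without 0 hpa replicate 2 or 24 hpa replicate 2, 1 and 0 without 24 hpa replicate 1, and 17 and 12 without 0 hpa replicate 1. Without 72 hpa replicate 1 or replicate 2, which only add to the estimate of spread, there were 65 and 33 or 66 and 33.

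**Figure D2:**
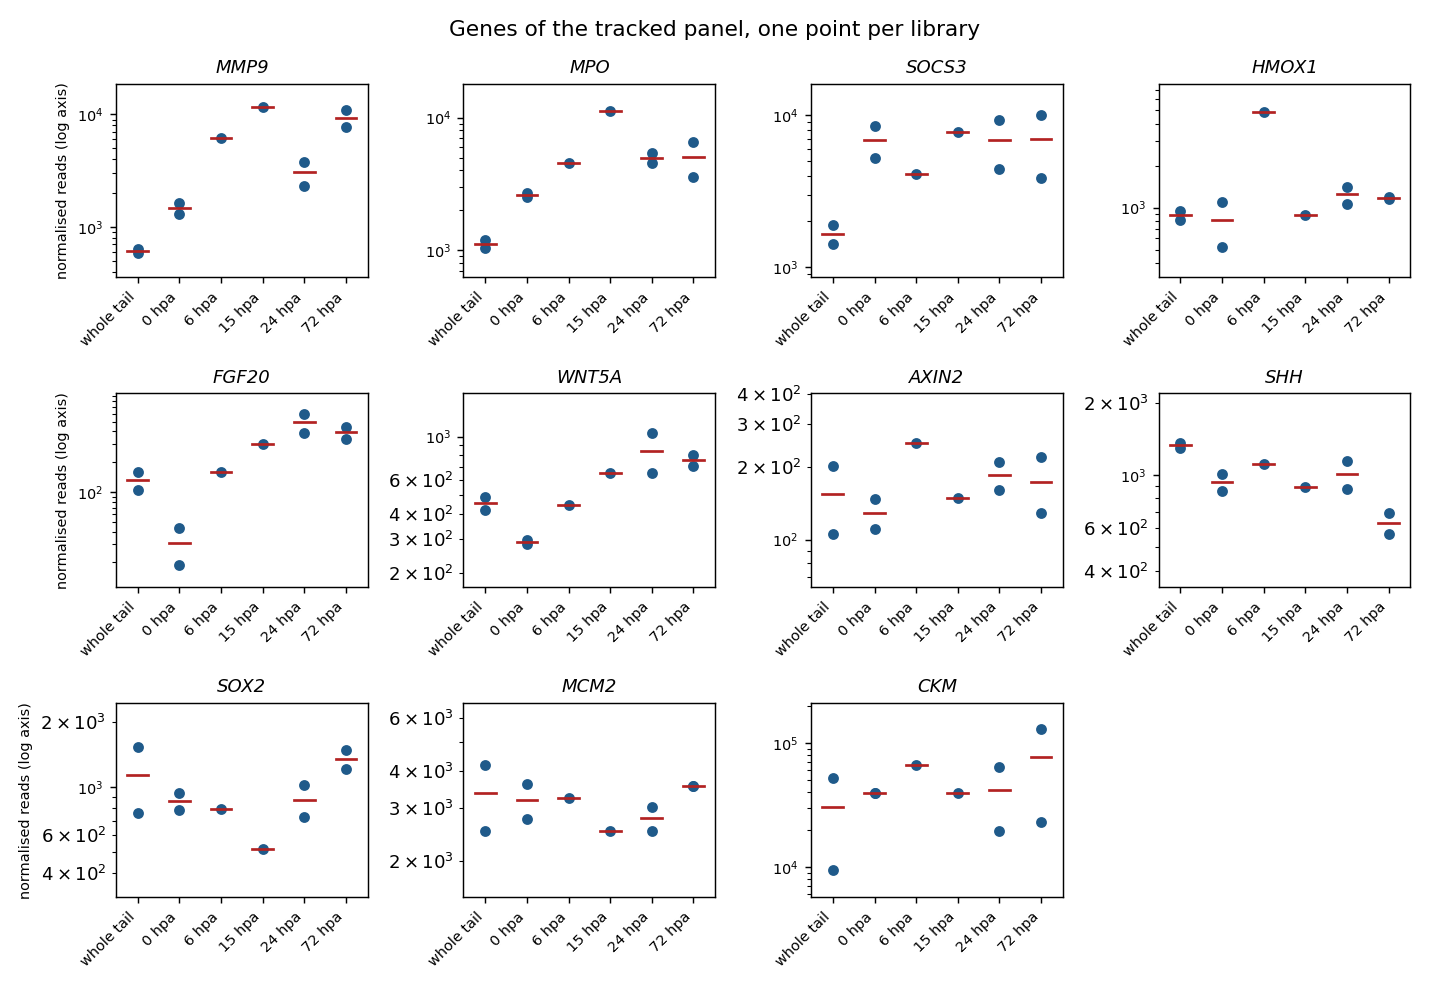
Normalised reads (log axis) of 11 genes fixed in advance, by group; each point is 1 library and each red bar the group mean. FGF20 was lowest at 0 hpa (31.35) and highest at 24 hpa (493.3), HMOX1 stood at 4861 in the 6 hpa library, and the CKM values of the 72 hpa libraries lay far apart (SD 76100 about a mean of 76980).

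The comparison of 72 hpa with 0 hpa held the most calls. Most of the erythroid and neuron genes and 13 of 25 mitosis genes fell, and 12 of 23 leukocyte genes rose. HBA-L2, an alpha globin, fell from 6410 ± 874 to 10.69 ± 5.5 normalised reads (SD, n = 2 each; log2 fold change -9.18, SE 0.66, limma adjusted p = 0.0027). HBZ (-7.49, SE 0.6) and HBE1 (-7.07, SE 0.8), further globins, fell too. Of 19 erythroid genes, 15 fell and 4 did not pass (median -3.75, camera adjusted p = 1e-14, and adjusted p = 0.55 with an estimated correlation). Relative to the 0 hpa mean, the erythroid median was already -1.02 and -1.79 in the whole tail libraries. Globins form a gene family, and where copies are near-identical, reads may be divided between them in ways the counting cannot resolve. ITLN1, an intelectin made by epidermal secretory cells of the tadpole, fell by 7.03 (SE 1.3). FUCOLECTIN, another lectin gene, fell by 8.31 (SE 0.788). For these limma gave adjusted p = 0.028 and 0.0046. The epidermis list held 3 genes that fell, ITLN1, FOXI1 (-3.05, SE 0.55) and ITLN2 (-6.92, SE 1.24). Its median was -0.43 (camera adjusted p = 0.04; adjusted p = 0.75 with an estimated correlation). That call held in 10 of 18 settings and was lost without 72 hpa replicate 2 (median -0.23), without either 0 hpa or whole tail replicate, under both other filters and against the whole tail (-0.39).

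Of 26 differentiated neuron genes, 17 fell, 1 rose and 8 did not pass (median -2.22, camera adjusted p = 5.7e-15; adjusted p = 0.34 with an estimated correlation). The enzyme of acetylcholine synthesis, CHAT, fell by 3.63 (SE 0.678). SLC18A3 (-3.43, SE 0.327) and the synaptic gene CPLX1 (-3.31, SE 0.362) fell as well, while GAD1.2, a glutamate decarboxylase copy, rose by 3.16 (SE 0.626). Of 25 mitosis genes, 13 fell, 12 did not pass and 22 were lower adjusted over the list alone. The list median was -1.03 (camera adjusted p = 9e-15; adjusted p = 0.55 with an estimated correlation). BIRC5.2, a component of the chromosomal passenger complex, fell from 2185 ± 392 to 691.4 ± 1.63 normalised reads (SD, n = 2 each). PRC1, a spindle midzone protein (-1.58, SE 0.275), and CCNA2, cyclin A2 (-1.48, SE 0.213), fell as well. DNA replication genes had a median of -0.37, and 2 of 30 fell (camera adjusted p = 0.001; adjusted p = 0.75 with an estimated correlation). MCM2, a replicative helicase subunit, had a log2 fold change of 0.18 (SE 0.266, limma adjusted p = 0.73).

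Leukocyte genes rose at 72 hpa in 12 of 23 cases (median 1.21, camera adjusted p = 6.1e-10; adjusted p = 0.33 with an estimated correlation), among them CSF1R (2.21, SE 0.162) and TLR2 (1.99, SE 0.467). Matrix proteases rose in 4 of 17 cases (median 0.76, camera adjusted p = 0.0013; adjusted p = 0.33 with an estimated correlation). MMP9 rose from 1459 ± 232 to 9340 ± 2380 normalised reads (SD, n = 2 each). FGF20 rose by 3.71 (SE 0.47, limma adjusted p = 0.011) and WNT5A, a noncanonical Wnt ligand, by 1.39 (SE 0.271, limma adjusted p = 0.031). Of the genes that met the rule for naming, UMOD.3, CHIT1, MYO1H, SCNN1B and HMX1 had the largest rises. UMOD.3, a uromodulin-like gene, had 3 reads in the 0 hpa libraries together, which gives a ratio of 337 with a 95% counting interval of 115 to 1630. CHIT1, a chitinase, rose by 5.75 (SE 1.16, limma adjusted p = 0.033), with 14340 ± 16700 normalised reads (SD, n = 2). MYO1H, SCNN1B, an epithelial sodium channel subunit, and HMX1, a homeobox gene, rose by 5.68, 5.57 and 5.48. With the whole tail as the reference, SCNN1B (3.73), FGF20 (1.58), WNT5A (0.72), CHAT (-2.02) and EGR1 (-0.09) did not pass.

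Immediate early genes were lower at 72 hpa (median -1; adjusted p = 0.75 with an estimated correlation), and EGR1 fell by 1.11 (SE 0.216). Their median was -0.02 against the whole tail. Anterior and trunk Hox genes had a median of 0.55 against 0 hpa and -0.75 against the whole tail (adjusted p = 0.75 with an estimated correlation for the former). The other camera calls were ribosome biogenesis, higher (0.38), and, lower, neural progenitors (-1.10), notochord and floor plate (-0.57), oxidative phosphorylation (-0.51), unfolded protein response (-0.50), V-ATPase subunits (-0.47) and endothelium (-0.43), with adjusted p between 0.75 and 0.79 with an estimated correlation. Of the 16 list calls at 72 hpa, 9 were lost in at least 1 fit without a library. Without 72 hpa replicate 1 the calls for anterior and trunk Hox, oxidative phosphorylation, unfolded protein response, V-ATPase and endothelium genes were lost, and without replicate 2 those for neural progenitor, notochord and ribosome biogenesis genes. The medians in 72 hpa replicates 1 and 2 were -0.86 and -0.18 for oxidative phosphorylation and -0.73 and -0.17 for the unfolded protein response. The endothelium call held in 12 of 18 settings and was also lost with a replicate block.

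In total, limma called 513 genes higher and 632 lower at 72 hpa, edgeR 446 and 564, and DESeq2 1011 and 1343. The limma counts were 58 and 102 without 72 hpa replicate 2, 185 and 426 without 72 hpa replicate 1, 74 and 79 without 0 hpa replicate 1, and 85 and 77 without 0 hpa replicate 2.

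**Figure D3:**
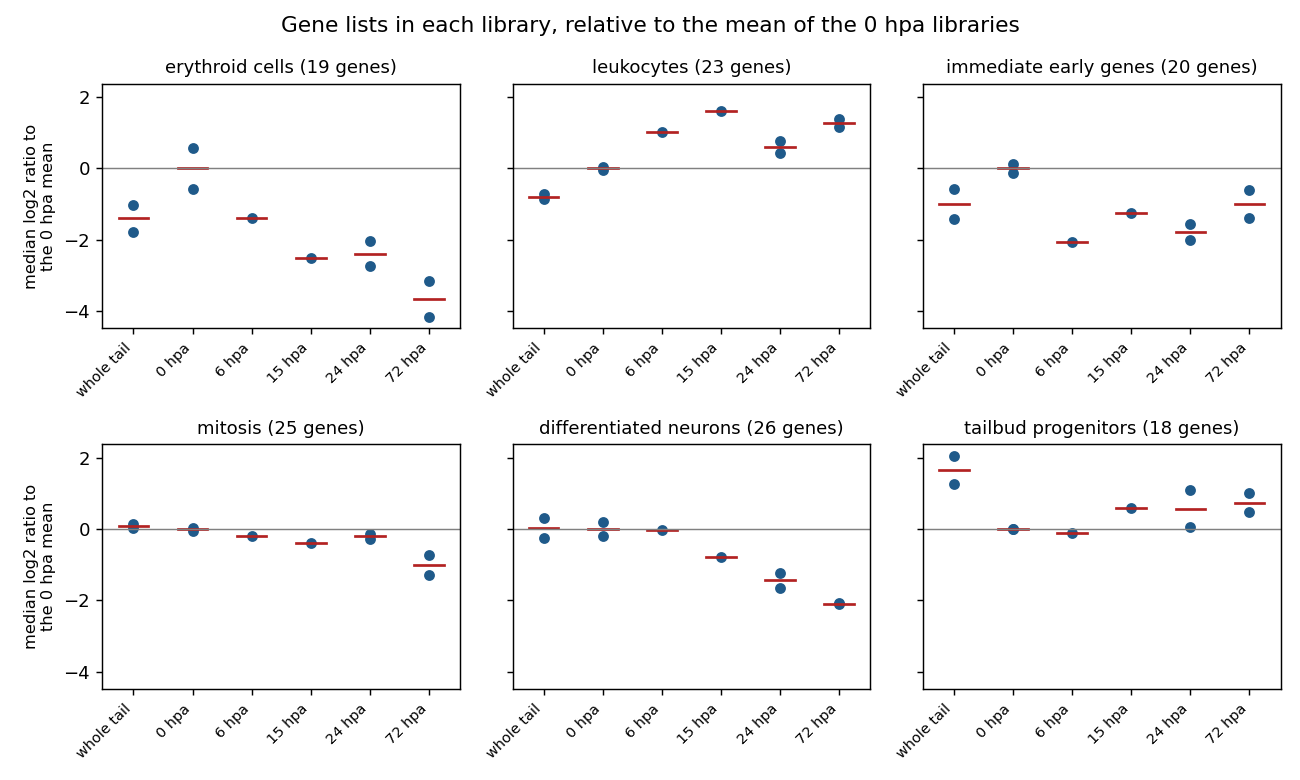
Median log2 ratio to the mean of the 0 hpa libraries over the tested genes of 6 lists, by group; each point is 1 library and each red bar the group mean. The 72 hpa libraries lay below the 0 hpa libraries for erythroid, mitosis and neuron genes, and the whole tail libraries lay above them for tailbud genes.

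Between 24 and 72 hpa, mitosis genes were lower and leukocyte genes higher at the later time as lists (adjusted p = 0.61 with an estimated correlation for both), with few single genes called. Of 25 mitosis genes 24 were lower in value and 21 lower adjusted over the list alone. Their median was -0.89 (camera adjusted p = 2.9e-18; adjusted p = 0.61 with an estimated correlation), and that of 26 neuron genes -0.70 (camera adjusted p = 1.1e-06; adjusted p = 0.61 with an estimated correlation). Leukocyte (0.60), immediate early (0.92), oxidative stress (0.61) and pigment cell genes (0.96) had higher medians, and erythroid (-1.39) and unfolded protein response genes (-0.47) lower ones, each with adjusted p = 0.61 with an estimated correlation. Oxidative phosphorylation (-0.23) and ribosome biogenesis genes (-0.39) were also called lower, with adjusted p = 0.85 with an estimated correlation. UMOD.3 had 0 reads in both 24 hpa libraries and 946.5 ± 658 normalised reads at 72 hpa (SD, n = 2), at least 231-fold higher at a floor of 3 reads per library. HBA-L2 (-6.11, SE 0.66), DNASE1L3, a secreted deoxyribonuclease (-3.37, SE 0.368), and SLC18A1, a vesicular monoamine transporter (-2.13, SE 0.196), fell. For these limma gave adjusted p = 0.039, 0.039 and 0.025.

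Here limma called 7 genes higher and 6 lower (1913 had an unadjusted p under 0.05), edgeR 1 and 1 (LOC101732051 and LOC100494341), and DESeq2 263 and 284. The limma counts were 0 and 1 without 0 hpa replicate 1 or 2, 0 and 4 without 72 hpa replicate 2, and 12 and 48 without 72 hpa replicate 1. They were 4 and 1 without 24 hpa replicate 1, 3 and 17 without 24 hpa replicate 2, and 2 and 2 without whole tail replicate 2. Of the 10 list calls, 3 were lost in at least 1 fit without a library, those for oxidative stress, oxidative phosphorylation and ribosome biogenesis genes.

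Of the 119 genes higher at 24 hpa, 99 were also higher at 72 hpa, and of the 54 lower, 43 were also lower. Independent lists of these sizes would share 3.41 and 1.91. All libraries were also simulated without any change, with 1 simulated 0 hpa group as the reference for both times. There, lists of these sizes taken by smallest p shared 62.6 and 18.4 genes on average over 20 draws (at most 72 and 26). Shared controls, and the 1 estimate of spread per gene that both comparisons use, can thus give overlap where nothing changes. The simulation did not separate these 2 sources. The observed 99 and 43 lay above the largest draws, but only 0.65 and 0.7 genes on average were called at 24 and 72 hpa in the simulations. They thus set no expectation for called genes, and the overlap is not read as a shared effect. With the whole tail as the reference for 72 hpa, 70 and 32 were shared, against 5.49 and 2.53 for independent lists, and 3 genes were called in opposite directions. Against the whole tail, 118 of the 119 genes higher at 24 hpa kept their sign and 60 passed, and 498 of the 513 genes higher at 72 hpa kept their sign and 373 passed. Of the lower genes, 53 of 54 and 626 of 632 kept their sign, and 23 and 473 passed. Because the later libraries are the same in both comparisons, most of the kept signs are built in. Simulated unchanged groups kept 103 of 119 and 434 of 513 higher genes and 51 of 54 and 570 of 632 lower genes on average. Under 1 gene passed in each, but few genes can pass where nothing changes. Those passing counts thus set no expectation for the observed ones.

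Fibrillar matrix, skeletal muscle, BMP and TGF-beta signalling, glycolysis and hypoxia, p53 and apoptosis, and trunk organ genes passed camera in none of the 6 comparisons. The skeletal muscle median ranged from -0.19 at 72 hpa to 0.52 at 6 hpa against 0 hpa, and CKM, muscle creatine kinase, had limma adjusted p = 0.82 and 0.97 there. SHH, SOX2 and AXIN2, a notochord and floor plate signal, a neural stem cell factor and a Wnt target, passed limma in no comparison. IL11 and PAX7 had no row under those symbols, and CCNB1, with group means of 0.9368 to 6.565 normalised reads, was under the filter.

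The authors' deposited table flags 5089 genes as changed and places 2511 of them in 8 clusters. In the authors' deposited table, cluster 1 (250 genes) held 14 of the 27 mitosis genes, cluster 4 (535 genes) 12 of the 26 neuron genes, and cluster 6 (487 genes) 15 of the 24 leukocyte genes. The median log2 ratio to 0 hpa at 72 hpa, computed from the normalised reads, was -1.34 for cluster 1 of the authors' deposited table, -1.93 for its cluster 4 and 1.07 for its cluster 6. How the clusters were formed is not stated. If they group genes by profile over these libraries, such medians are built in and are no separate evidence. Of the limma calls, 65 of 65 at 15 hpa, 173 of 173 at 24 hpa and 1140 of 1145 at 72 hpa carried the flag of the authors' deposited table. Over all genes, 5089 of 26550 carried it. Flag and calls belong to the same libraries, so this overlap is no independent support.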

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

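The results of the next paragraph were picked out because 72 hpa and 24 hpa, which share the 0 hpa reference, differed by the test of their difference. The 3 patterns after it were chosen as ones to follow up, after the results were seen. The fits without 1 library and the camera test with an estimated correlation were planned; the other tests that weigh explanations were chosen after the results were seen.

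The lists that differed had median log2 changes from 24 to 72 hpa of 0.916 (immediate early genes), 0.604 (leukocytes), 0.606 (oxidative stress response), -0.885 (mitosis), -0.704 (differentiated neurons), -0.231 (oxidative phosphorylation), -0.389 (ribosome biogenesis), -0.474 (unfolded protein and heat shock response), -1.39 (erythroid cells) and 0.964 (pigment cells and neural crest). None of these 10 list calls held with an estimated correlation (smallest adjusted p = 0.61). Named genes among the 13 limma calls were UMOD.3 (fitted log2 change 9.69, which is no bound because 24 hpa is at 0 reads), HBA-L2 (-6.11), DNASE1L3 (-3.37) and SLC18A1 (-2.13). None of these named genes passed edgeR with TMM, which called only LOC101732051 and LOC100494341. DESeq2 called 12 of the 13 in the same direction.

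The mitosis list was called lower at 72 hpa than at 0 hpa (median -1.03, 13 of 25 genes falling; adjusted p = 0.55 with an estimated correlation). Depth alone does not account for it, since the median was -0.983 after thinning every library to 1 depth, nor does a single 72 hpa library, since the smaller fall without either was -0.712 and both stayed called at the preset correlation. Loss of neural tissue in proportion to the neuron list would need a median of -0.684 at 24 hpa, where it was -0.197 (95% bootstrap interval over genes -0.3 to -0.125), a test that takes the ratio of the lists as fixed. The interval does not measure the spread between libraries, whose mitosis medians at 24 hpa were -0.122 and -0.269. Age stays open and cannot be told apart from regeneration, because 0 uncut groups of the age at 72 hpa were in the design. A lower share of dividing cells, whether from age or regeneration, is thus a hypothesis. DNA replication genes fell less, with medians of -0.313 and -0.402 in the 72 hpa libraries against -0.712 and -1.3 for mitosis. MCM2 had a log2 fold change of 0.18 (limma adjusted p = 0.73). Such values go less well with that hypothesis.

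The erythroid list was called lower at 72 hpa as well (15 of 19 genes falling; adjusted p = 0.55 with an estimated correlation). Without 0 hpa replicate 2, the library with the largest globin share, the list median was still -3.18. That fit cannot address extra blood in both 0 hpa libraries (globin 1.36% and 4.17%, against 0.774% and 0.614% in the whole tail). Relative to the 0 hpa mean, list medians were -1.02 and -1.79 in the whole tail libraries. They were -4.18 and -3.16 at 72 hpa, so a smaller fall remained against the whole tail. From whole tail to 72 hpa, HBA-L2 went from 3724 to 10.69 normalised reads on average and HBD from 53940 to 27540. A lower share of red cells alone would lower all globins alike, but their falls differed by more than their errors. Cochran Q per degree of freedom was 8.47 over the 13 tested globins, with errors treated as known. Falls ran from -9.18 for HBA-L2 to -3.29 for HBD, and HBG2 stood at 0.19 (SE 1.31). Globins also changed unequally between whole tail and 0 hpa, which share tadpoles and so do not differ in age. HBD averaged 53940 and 305000 normalised reads there, HBA3 78030 and 434500, and HBA-L2 3724 and 6410. At 0 hpa their SDs (n = 2) were 252000, 363000 and 874. Unequal falls at 72 hpa thus do not by themselves point to age. A lower share of red cells may still account for part of the fall, and reads shared between globin copies were not tested. A change in which globins are transcribed with age, added to a lower share, is a hypothesis that no group of the design tests.

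The anterior and trunk Hox, posterior Hox and tailbud lists were called lower at 0 hpa than in the whole tail (adjusted p = 0.13, 0.29 and 0.13 with an estimated correlation). No single library decided this at the preset correlation, since the highest camera adjusted p of the 3 lists over the fits without 1 of the 4 libraries was 1.8e-05. Less neural tissue at 0 hpa would lower neuron genes by about the same amount (-1.36), but their median was -0.0826 (95% bootstrap interval over genes -0.27 to 0.206). This interval does not measure the spread between libraries. The neural progenitor list was called lower there, at a median of -0.40 (adjusted p = 0.66 with an estimated correlation). That fall rested on whole tail replicate 1. Relative to the 0 hpa mean, list medians were 0.737 and -0.0156 in whole tail replicates 1 and 2. Without replicate 1 the median was 0.0156, so a smaller share of progenitors as a part is neither shown nor excluded. The position of the tissue along the tail, which the design names, stays open and untested, as the whole tail holds the tip and the 0 hpa tissue does not.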

How the results depend on the processing

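The alternatives chosen after the data were seen are TMM scaling under limma, thinning, the pseudocounts 0.5 and 10, and edgeR with TMM (planned as the test for counts); the others were planned. Counts are given as higher and lower, in the order 0 hpa against whole tail, then 6, 15, 24 and 72 hpa against 0 hpa, then 72 against 24 hpa; the cause of a change was not tested unless stated. Without a low-count filter, limma called 10 and 3, 121 and 10, 134 and 28, 54 and 21, 137 and 95, and 8 and 19. DESeq2 called 198 and 128, 101 and 41, 410 and 417, 521 and 594, 1011 and 1343, and 263 and 284. For the settings that follow, counts equal to the main ones or within 1.5 times of them are left out unless stated. edgeR with TMM called 2 lower at 0 hpa, 68 higher at 15 hpa, and 1 and 1 between 24 and 72 hpa. With DESeq2 size factors it called 12 lower at 15 hpa and 1 and 1 between 24 and 72 hpa. Its counts of 83 and 36 at 24 hpa and 437 and 556 at 72 hpa were within that range. TMM scaling under limma, and the fit of the 8 duplicated libraries, each gave 2 lower at 0 hpa. For 72 against 24 hpa, thinning gave 2 higher, a pseudocount of 0.5 gave 3 and one of 10 gave 15; the latter gave 8 lower at 15 hpa. With only the 4 libraries compared, a fit of fewer samples, counts were 49 and 25 at 24 hpa, 240 and 235 at 72 hpa, and 1 and 0 between them. Against the whole tail, 92 genes were higher at 15 hpa and 825 at 72 hpa. The stricter filter of 1 CPM kept all 12 counts within 1.5 times.

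Fits without 1 replicate also have fewer samples. Their ranges were 0 to 3 higher and 0 to 1 lower at 0 hpa against the whole tail, 0 to 2 and 0 to 0 at 6 hpa, 0 to 12 and 1 to 9 at 15 hpa, 0 to 96 and 0 to 46 at 24 hpa, 58 to 414 and 77 to 548 at 72 hpa, and 0 to 12 and 1 to 48 for 72 against 24 hpa. At 15 hpa the lowest came without 0 hpa replicate 1, tied for higher genes by 0 hpa replicate 2. At 24 hpa they came without 0 hpa replicate 2 or 24 hpa replicate 2. At 72 hpa they came without 72 hpa replicate 2 (higher) and 0 hpa replicate 2 (lower). For 72 against 24 hpa they came without either 0 hpa replicate. There 72 hpa replicate 2 tied for higher genes and 24 hpa replicate 1 for lower genes. Whole tail and 0 hpa share tadpoles by design and were fitted as independent, but the labels do not say that numbers pair the libraries, and the correlations of same-numbered deviations (-0.13 to 0.27, and -0.009 for whole tail and 0 hpa) leave this open. With a replicate block, counts were 0 and 0 at 0 hpa, 91 and 56 at 24 hpa, 512 and 738 at 72 hpa, and 18 and 27 between them.

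These values changed sign or direction of camera. Against the whole tail, KRT16 at 15 hpa was -0.05952, and list medians were 0.31 (erythroid, 6 hpa); -0.164, -0.416, -0.764 and -1.19 (FGF, posterior Hox, anterior and trunk Hox, tailbud, 15 hpa); 0.786, -0.109, -0.57, -0.815 and -1.15 (inflammatory and the same 4, 24 hpa); and -0.0226, -0.824, -0.749 and -0.643 (immediate early, posterior Hox, anterior and trunk Hox, tailbud, 72 hpa). The others are given as ranges over fits without 1 replicate. At 0 hpa they were -0.264 to 0.152 (DNA replication), -1.76 to 0.18 (myogenic progenitors), -0.737 to 0.0156 (neural progenitors), -1.13 to -0.0892 (pigment cells, a median that kept its sign, at -0.175 where camera changed direction) and -0.0152 to 0.415 (ribosome biogenesis), and -1.05 to 1.54 (muscle). At 72 hpa muscle went from -1.35 to 1.07; against 24 hpa it went from -1.03 to 1.18, and oxidative phosphorylation from -0.582 to 0.0929. Lists with no call by the main test count here where the alternative called them. Of the camera calls, 10 of 16, 7 of 11, 7 of 13, 7 of 19, 6 of 16 and 7 of 10 held in every setting of scaling, filter, samples and reference, and none with an estimated correlation. Depth limits genes near the floor of 3 reads.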

Other observations

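Skeletal muscle genes varied between replicates more than between groups. CKM stood at 30670 ± 30000 normalised reads in the whole tail and at 76980 ± 76100 at 72 hpa, but at 39750 ± 32.8 at 0 hpa (SD, n = 2 each). The authors' deposited table holds a cluster 5 of 241 genes. Its median log2 ratio to 0 hpa was -1.86 in the 15 hpa library and -0.15, -0.02 and 0.37 at 6, 24 and 72 hpa. With 1 library at 15 hpa this dip has no replicate check. The dip is built in if the cluster was formed from these same libraries.

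Inside the notochord list, fitted changes at 24 hpa went in both directions, but among the genes named here only the rises passed. NOT, KRT8 and KRT18 rose by 2.56 (SE 0.194), 1.53 (SE 0.228) and 1.47 (SE 0.208), while the collagens COL9A1 and COL9A2 had log2 fold changes of -1.50 (SE 0.285) and -1.31 (SE 0.294) that did not pass over all genes (limma adjusted p = 0.066 and 0.094). At 72 hpa COL9A1 (-1.81, SE 0.285), COL9A2 (-1.73, SE 0.294) and COL8A1 (-1.55, SE 0.221) fell, and NOT rose by 1.37 (SE 0.194), to 699.9 and 797.2 normalised reads, beside 685.4 and 689.2 in the whole tail libraries. These genes were chosen after their values were seen. Outside the lists that were called, INHBA, a subunit of activin, rose by 3.41 at 24 hpa (SE 0.397, limma adjusted p = 0.021), and IL6ST and STAT3.1, parts of cytokine signalling, rose by 2.05 (SE 0.232) and 1.81 (SE 0.234).

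A DESeq2 likelihood ratio test over the 6 groups called 3513 genes, of which 3467 carry the flag of the authors' deposited table. That table flags 5089. The test used the same libraries, so this overlap is no independent support.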
